A study of Homo sapiens with 75 samples.

How the data were processed

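Total RNA including small RNA was extracted with a column kit, 100 ng was ligated to tags and hybridised without amplification, and barcodes were counted on the nCounter panel, per the labels' protocols, which give an RNA integrity number above 8.5 for the samples. The deposited values are log2 values, and the normalization that the authors applied is not given in the sources used here. Both deposited tables held the same values (largest difference 0), so 1 was used. Every value had the form of log2(1 + count × a factor), with 1 factor per sample, and 100% of the values gave whole counts within a tolerance of 0.001 counts once the factor was recovered. The factors nearly equalised the geometric mean of all 800 probes (coefficient of variation 7.23% between samples) but not the summed normalized count (51.6%). Factors ran from 0.352 to 3.07 in the SCLC lines and reached 5.45 in NCI-H28, so 1 count there stands for more normalized counts. The tables hold no control probes. The p-values measure only the spread between these samples, since the labels do not say that samples came from separate cultures, and each line was measured once.

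Groups were taken from the labels. The growth protocol speaks of 63 SCLC lines where 64 samples are labelled SCLC, and A549, which it names, is not analysed here. NCI-H660 and NCI-H720, labelled SCLC, are known elsewhere as a prostate small cell carcinoma and a lung carcinoid, and results were recomputed without them. In 10 probes more than 1 miRNA is named, and these are given as shared. The floor was the median of all values, 3.82 log2 or 13.1 normalized counts. A background level was added after the data were seen, at the floor plus 2 background SDs of 0.972 log2, which gave 5.76 log2 or 53.3 normalized counts. A fold with 1 group mean below that level is given as at least the fold between the other mean and the level. This bounds group means and not each sample, and no fold is given where both means lie below. Differences beside the adjusted p of an alternative are fitted values, and for such miRNAs they are no bounds. Differences are SCLC minus comparator on the log2 scale with a pseudocount of 1, which understates folds of low miRNAs. The 2 fibroblast lines correlated at r = 0.978, the lung samples at 0.969 and the NSCLC lines at 0.806 over 201 miRNAs above background in at least 16 samples, and no pair lay within counting noise.

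Differences were tested with limma 3.58.1 (R 4.3.3), lmFit and eBayes on the log2 values, in 1 group-means model of the 75 samples, since each comparator group had only 2 samples, with 68 residual and 4.04 prior degrees of freedom. A probe was tested if it lay above the floor in at least 2 samples, which left 789, with Benjamini-Hochberg adjustment and a threshold of 0.05. The pooled spread is mostly that of the SCLC lines, and where 1 comparator was left out the other was assumed to vary like the other groups. Fixed miRNA lists with at least 3 members were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, which asks whether members move one way on balance. The 20 lists were neuronal and neuroendocrine, miR-200, other epithelial, miR-183, miR-17-92 and paralogs, fibroblast and mesenchymal, endothelial, blood and immune, muscle, liver, let-7, miR-34 with miR-449, miR-29, miR-30, miR-15/16, HOX, pluripotency, DLK1-DIO3, C19MC and miR-506 to miR-514 miRNAs. A gene table of the assembly GRCh38.p14, used for names and neighbours only, placed 47 of the 48 DLK1-DIO3 list names between DLK1 and DIO3. The probes gave no coordinates.

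The design, the lists, the alternatives and the rule for named miRNAs were fixed before the data were examined, and the design had allowed for linear values. The rule took, for each tested comparison, the 10 highest and 10 lowest differences among called miRNAs for which each comparator lay on the same side of the SCLC median, and up to 4 members of each list by smallest adjusted p. For the made-resistant lines and single samples it took the 10 largest mean differences, and for the variation the 10 largest SDs among miRNAs with a median above the floor. A short set of markers, among them miR-375, miR-9, miR-21 and let-7a, was always allowed. Shared names between comparisons, component ends and the NCI-H82, COR-L32 and adrenal examples were named after their values were seen.

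For NCI-H69 and the single samples no test was made. Clusters of the SCLC lines were sought with mclust 6.1.1, as 2 components preferred by BIC with means over 2 pooled SDs apart. Every measure met the limit on the means (lowest 2.41 pooled SDs), so BIC alone decided. From 1 to 2 components BIC rose from -325.9 to -297.3 for miR-375, but only from -229.7 to -228.4 for miR-31-5p. Correlations had two-sided permutation p-values from 100000 resamples, or from all orders (exact) in cells of fewer than 10 lines, with Benjamini-Hochberg adjustment over 37 tests. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The limma step was tested on simulated data with 200 of 789 miRNAs changed in each comparison. Of 50 miRNAs changed by 1 log2 unit it recovered 12 in each comparison, of 50 changed by 2 units 39, 35 and 38 in the lung, fibroblast and NSCLC comparisons, of 50 changed by 4 units 48 in each, and of 50 changed by 6 units all 50. Among 589 unchanged miRNAs it called 5, 4 and 7. Alternatives changed the filter, the scaling (centring each sample on 87 probes above the floor in every sample, quantile normalization, the 100 most abundant miRNAs), the handling of low values, the samples, the listing run as a block and the model (voom on recovered counts). Counts of called miRNAs under an alternative are also given as the percent of the miRNAs tested there.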

Results

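MicroRNA (miRNA) abundance was measured in 75 human RNA samples with nCounter, an assay that counts fluorescent barcodes hybridised to each miRNA without amplification, using a panel of 800 miRNA probes. The samples came from 64 lines labelled small cell lung cancer (SCLC), a neuroendocrine lung tumour, 3 lines made resistant from the SCLC line NCI-H69, and 2 non-small cell lung cancer (NSCLC) lines. The remaining samples were 2 lung fibroblast lines (MRC-9 and WI-38), 1 mesothelioma line (NCI-H28), 2 samples of normal lung RNA and 1 of normal adrenal RNA. The NSCLC lines were NCI-H1650 and NCI-H2066, and the labels describe NCI-H2066 as a mixture of both tumour types. Total counts per sample ran from 32140 to 678107 in the SCLC lines, 409977 to 534526 in normal lung, 155175 to 172857 in the fibroblasts and 236109 to 236530 in the NSCLC lines. They ran from 242313 to 307598 in the made-resistant lines and were 99933 in normal adrenal and 39143 in NCI-H28. A background level of 5.76 on the log2 scale, 53.3 normalized counts, was exceeded by a median of 145.5 miRNAs per SCLC line, by at most 204 in normal lung and by 93 to 118 in the NSCLC lines.

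After the authors' scaling, the summed normalized count still differed between groups. It was 200259 ± 87954 in the SCLC lines (SD, n = 64), 586793 ± 51124 in normal lung (n = 2), 283335 ± 44949 in the fibroblasts (n = 2), 116089 ± 19464 in the NSCLC lines (n = 2) and 109139 ± 19981 in the made-resistant lines (n = 3). The titles are listed in 6 alphabetical runs, which may be assay batches, although the labels name none. Run 1 holds normal lung, the fibroblasts, normal adrenal, NCI-H28 and 17 SCLC lines with a summed normalized count of 270271 ± 90049, and run 5 holds the NSCLC lines, the made-resistant lines and 8 SCLC lines with 113079 ± 44966.

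**Figure D1:**
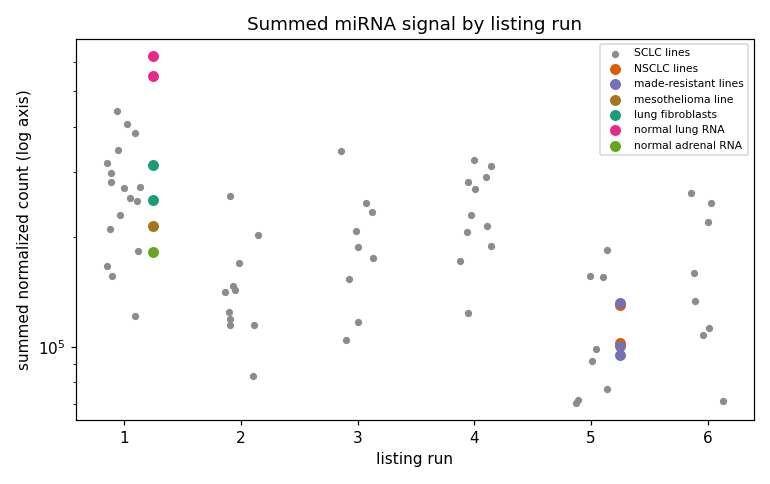
Summed normalized count per sample (vertical log axis) against the listing run of the sample titles (horizontal axis), 1 point per sample, with symbols for the sample groups. SCLC lines of run 1 average 270271 and those of run 5 average 113079, and normal lung averages 586793.

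The comparison with normal lung set the SCLC lines beside whole tissue of the organ in which these tumours arise. The neuronal miR-9-5p, a regulator of neural progenitors with the sequence UCUUUGGUUAUCUAGCUGUAUGA, rose to 10.87 ± 1.58 (log2, SD, n = 64) in SCLC lines from 4.98 ± 0.10 in normal lung (n = 2), at least 34.5-fold, and was higher in 64 of 64 lines. The sensory and neuroendocrine cluster members miR-182-5p and miR-96-5p rose by 2.97 and 2.76 log2 units (SE 0.99 for the former), 7.86-fold and 6.79-fold, in 60 and 62 lines. Neither was called with only the 17 SCLC lines of run 1 (2.81 and 2.91, adjusted p = 0.197 and 0.233). The call of miR-96-5p also ended without NCI-H660 and NCI-H720 (adjusted p = 0.0509) and with only the 2 groups compared in the fit (adjusted p = 0.0571). Also, miR-301a-3p was higher in 64 of 64 lines, at least 19.7-fold, and miR-196b-5p, encoded in a HOX gene cluster, in 61 lines, at least 6.70-fold. The neuroendocrine marker miR-375 (UUUGUUCGUUCGGCUCGCGUGA) was 9.92 ± 2.92 in SCLC lines and 7.12 ± 1.12 in normal lung, a difference of 2.80 (SE 1.96) that did not pass the test (adjusted p = 0.380). Its levels in SCLC lines fell into separate clusters, 14 lines with a mean of 5.04 and 50 with 11.28, so the mean of all lines describes neither.

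miRNAs of blood, stromal and endothelial cells, all of which are present in whole lung tissue, were far lower in SCLC lines. The erythroid miR-451a fell by at least 1200-fold, from 15.99 ± 0.32 to 2.88 ± 0.82, and the myeloid miR-223-3p by at least 399-fold, each in 64 of 64 lines. The endothelial miR-126-3p was lower by 387-fold, at 6.65 ± 1.58 against 15.25 ± 0.13. Smooth muscle and fibroblast miRNAs fell likewise, with miR-145-5p lower by at least 319-fold and miR-143-3p by 243-fold, each in 64 lines. Also, miR-30a-5p was lower by 92.2-fold and miR-29a-3p, which targets collagen transcripts, by 33.5-fold. The p53 target miR-34a-5p was lower by at least 26.2-fold, and miR-21-5p, an abundant miRNA often raised in carcinomas, was lower in SCLC lines by 20.9-fold, both in 64 lines. After quantile normalization neither call held, at fitted differences of -3.54 (adjusted p = 0.0749) and -2.49 (adjusted p = 0.0964), against -5.38 and -4.39 before. C19MC, the primate-specific chromosome 19 cluster, had 1 large change, in miR-518b, which was 4.11 in SCLC lines and 11.33 in normal lung.

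By fixed list, 8 of 11 blood and immune miRNAs fell in SCLC lines (8 lower when adjusted over the list alone), as did 9 of 13 fibroblast and mesenchymal miRNAs (9), 5 of 5 of the miR-30 family (5) and 3 of 3 of the miR-29 family (3). These 4 lists passed the camera test, and the blood and fibroblast lists also passed with an estimated correlation (adjusted p = 2.50e-11 and 0.00288). The miR-30 and miR-29 lists did not (adjusted p = 0.132 with an estimated correlation for each), although they did after centring (0.00507 and 0.0200). Members of other lists fell without their list passing camera. These were the miR-34 and miR-449 family, 4 of 7 (adjusted p = 0.0526), the miR-15/16 family, 2 of 5 (miR-195-5p and miR-497-5p, adjusted p = 0.0871), the let-7 family, 2 of 9 (let-7c and let-7g-5p, adjusted p = 0.0871), and other epithelial miRNAs, 2 of 6 (miR-203 and miR-205-5p, adjusted p = 0.265). Fry, which does not compare a list with other miRNAs, called the miR-34 and miR-449 (adjusted p = 6.91e-06), miR-15/16 (0.0121) and other epithelial (0.0115) lists lower but not let-7 (0.0748). It called the neuronal (0.0121), miR-183 (0.0148) and HOX (0.0126) lists higher. The calls of let-7c (-3.51), let-7g-5p (-2.43), miR-203 (-4.59) and miR-205-5p (-5.28) depended on the scaling. After centring they were -1.77, -0.70, -2.86 and -3.55 (adjusted p = 0.0591, 0.287, 0.0522 and 0.0682), and after quantile normalization -1.99, -0.51, -2.99 and -3.55 (adjusted p = 0.119, 0.703, 0.0955 and 0.218). With voom let-7g-5p, miR-203 and miR-205-5p were not called either (adjusted p = 0.223, 0.0606 and 0.0680). With the 17 SCLC lines of run 1 let-7c and let-7g-5p were not (adjusted p = 0.208 and 0.0643), nor was let-7c with the run as a block (-2.37, adjusted p = 0.0792). None of these 4 passed without either normal lung sample (adjusted p from 0.0745 to 0.324). Centring each sample shifted all differences of this comparison alike, with the median of all miRNAs going from 0.06 to 1.80. Through this shift the medians of the let-7 (-1.42), miR-34 and miR-449 (-1.50) and other epithelial (-0.93) lists turned to 0.31, 0.23 and 0.81. Relative to all miRNAs they stayed at -1.49, -1.57 and -0.99. After quantile normalization the let-7 median was 0.29, which is 0.20 relative to all miRNAs, so its direction was turned by that scaling. Adjusted over the list alone, 4 of the miR-34 and miR-449, 3 of the miR-15/16, 3 of the let-7 and 2 of the other epithelial miRNAs were lower. Among neuronal and neuroendocrine miRNAs 2 of 13 rose (miR-9-5p and miR-153, adjusted p = 0.0871 for the list), and in the miR-183 cluster 2 of 3 (3 when adjusted over the list alone, adjusted p = 0.0839).

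No member was called in the miR-200 family, epithelial miRNAs that restrain mesenchymal transition, where 0 of 5 passed by limma and the median difference of -0.21 (-0.28 relative to all miRNAs, centred or not) became 0.98 (0.89 relative to all miRNAs) after quantile normalization. The miR-200 family mean also fell into separate clusters of SCLC lines, 14 with a mean of 3.94 and 50 with 10.94. No member of the miR-17-92 cluster and its paralogs passed either (0 of 11), with a median difference of 0.86 (0.80 relative to all miRNAs, centred or not) that became 2.58 after quantile normalization and 1.53 with the listing run as a block. With that block camera also called the miR-17-92 (adjusted p = 0.00189), neuronal (0.0324) and miR-183 (0.0484) lists higher and the miR-34 and miR-449 list (0.0165) lower in SCLC lines. After centring it called the let-7 (0.0288) and the miR-34 and miR-449 (0.0386) lists lower relative to all miRNAs. None of these 6 calls passed with an estimated correlation, where the adjusted p was 0.246, 0.205, 0.352 and 0.0555 with the block and 0.440 for both lists after centring. In the lists of the imprinted DLK1-DIO3 cluster 1 of 56 rose (miR-370), in C19MC 2 of 43 rose (miR-520a-3p and miR-518c-3p) and 2 fell (miR-518b and miR-525-3p), and in the HOX clusters 1 of 6 rose (miR-196b-5p). Both group means of miR-520a-3p and of miR-518c-3p lay below background, as did the SCLC median of miR-370 (4.14). Of the muscle list 2 of 7 fell (miR-1 and miR-133a, neither called after centring, at adjusted p = 0.325 and 0.288), of the pluripotency list 1 of 10 (miR-302b-3p), and of the X-linked miR-506 to miR-514 list 0 of 21. Adjusted over the list alone, these counts were 0 for DLK1-DIO3, 1 higher and 2 lower for C19MC, 3 higher for the HOX clusters, 2 lower for muscle, 1 lower for pluripotency and 0 for the miR-17-92, miR-200 and miR-506 to miR-514 lists. The single endothelial miRNA fell and the single liver miRNA, miR-122-5p, was not called, at a difference of -0.43 (adjusted p = 0.661). The median differences of the muscle (-0.24) and pluripotency (-0.09) lists turned above 0 through the shift of all miRNAs by centring and stayed at -0.31 and -0.15 relative to all miRNAs.

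In limma, 123 of 789 miRNAs passed an adjusted p of 0.05 between SCLC lines and normal lung, 32 higher and 91 lower, of which 6 and 79 had at least 1 group mean above background. Adjusted p was 1.34e-05 for miR-9-5p, 0.0252 for miR-182-5p, 0.0461 for miR-96-5p, 1.79e-07 for miR-301a-3p, 0.0169 for miR-196b-5p, 2.58e-32 for both miR-451a and miR-223-3p and 2.69e-19 for miR-518b. It was 8.60e-10 for miR-126-3p, 6.60e-14 for miR-145-5p, 2.48e-12 for miR-143-3p, 4.82e-06 for miR-30a-5p, 0.000219 for miR-29a-3p, 0.000794 for miR-34a-5p and 0.000448 for miR-21-5p. Without normal lung replicate 1 the count was 62, and the calls of miR-182-5p (2.12, adjusted p = 0.552), miR-96-5p (2.55, adjusted p = 0.393), miR-196b-5p (4.65, adjusted p = 0.199), miR-34a-5p (-4.86, adjusted p = 0.0836) and miR-21-5p (-4.07, adjusted p = 0.0569) ended. Without replicate 2 it was 85, and miR-182-5p (3.83, adjusted p = 0.0620), miR-96-5p (2.98, adjusted p = 0.197) and miR-196b-5p (4.72, adjusted p = 0.154) lost their calls again. Centring each sample moved the split to 430 higher and 43 lower, with 53 and 43 above background. The split was 40 higher and 49 lower after quantile normalization, 226 and 47 after centring on the 100 most abundant miRNAs, 390 and 44 with voom, and 229 and 47 with centring and the listing run as a block. It moved the other way, to 8 higher and 111 lower, with low values set to the floor.

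**Figure D2:**
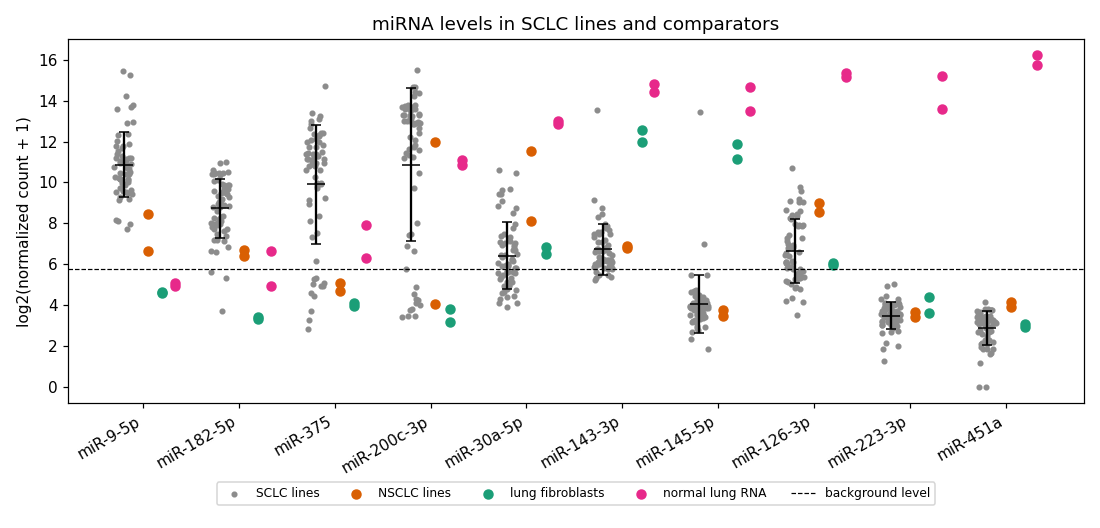
Level (vertical axis, log2 normalized count) of 10 miRNAs (horizontal axis) in SCLC lines (points, with mean ± SD), NSCLC lines, fibroblast lines and normal lung, with the background level dashed. The erythroid miR-451a averages 2.88 in SCLC lines against 15.99 in normal lung, and miR-9-5p averages 10.87 against 4.98.

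The fibroblast lines gave a comparison with non-cancer cells grown in culture, which lack the blood and endothelial cells of whole lung. All 3 miR-183 cluster miRNAs and 3 of 13 neuronal and neuroendocrine miRNAs were higher in SCLC lines, and the neuronal list did not pass with an estimated correlation (adjusted p = 0.121). The level of miR-9-5p was at least 34.5-fold higher (64 of 64 lines), that of miR-375 at least 17.8-fold (61 lines), and that of miR-95 at least 10.9-fold (63 lines). In the miR-183 cluster miR-183-5p was 9.60 ± 1.48 against 3.58, at least 14.3-fold higher (64 lines), with miR-96-5p and miR-182-5p higher by at least 8.63-fold and 7.91-fold (63 and 64 lines). The epithelial miR-200c-3p was 10.87 in SCLC lines and 3.48, below background, in fibroblasts, at least 5.11 log2 units apart, and lay above both fibroblast lines in 60 lines. It missed the threshold (adjusted p = 0.0512), with an SD of 3.74 among SCLC lines.

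Fibroblast and mesenchymal miRNAs were lower in SCLC lines. Among them miR-145-5p fell by at least 54.2-fold (63 of 64 lines), the probe shared by miR-199a-3p and miR-199b-3p by at least 63.6-fold (62 lines) and miR-143-3p by 47.5-fold (63 lines). The level of miR-100-5p was 6.07 in SCLC lines and 13.34 in fibroblasts, a difference of -7.28 (64 lines), and miR-221-3p, which targets the cell cycle inhibitor p27, was lower by 123-fold (64 lines). The collagen-targeting miR-29a-3p and miR-29b-3p fell by 50.4-fold and 41.7-fold, each in 64 lines, and miR-155-5p by 13.9-fold (64 lines). In the DLK1-DIO3 cluster 24 of 56 members fell and none rose, led by miR-337-5p at 4.89 against 10.45, at least 25.7-fold (63 lines).

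By list, 10 of 13 fibroblast and mesenchymal miRNAs fell (11 when adjusted over the list alone), 24 of 56 DLK1-DIO3 miRNAs fell (32) and 2 of 3 of the miR-29 family fell. In the neuronal and neuroendocrine list 3 of 13 rose, in the miR-183 cluster 3 of 3, in the miR-17-92 cluster and paralogs 1 of 11 (miR-25-3p, and 5 when adjusted over the list alone), and in the miR-200 family 0 of 5 (5 when adjusted over the list alone, median difference 5.26). All 7 lists passed the camera test. With an estimated correlation the fibroblast list (adjusted p = 0.000349) and the miR-183 cluster (adjusted p = 0.0241) still passed, and the others did not. Their values were adjusted p = 0.121 with an estimated correlation for the DLK1-DIO3, neuronal and miR-29 lists, 0.377 for the miR-200 family and 0.392 for the miR-17-92 list. Of these, the miR-17-92 list passed with the run as a block (0.0303) and the miR-29 list after centring (0.0376). In the remaining lists 1 of 11 blood and immune miRNAs rose (miR-486-3p) and 1 fell (miR-155-5p). In the miR-34 and miR-449 family 1 of 7 fell (miR-34a-5p, not called with voom, adjusted p = 0.0910). Of HOX miRNAs 1 of 6 rose (miR-196b-5p) and of C19MC 1 of 43 (miR-516a-5p). Of the miR-506 to miR-514 list 2 of 21 rose (miR-892a and miR-508-5p, and 1 when adjusted over the list alone). Both group means of miR-516a-5p, miR-892a and miR-508-5p lay below background. The calls of miR-34a-5p and miR-196b-5p ended when either fibroblast line was left out. No member passed in limma among other epithelial (6), muscle (7), let-7 (9), miR-30 (5), miR-15/16 (5), pluripotency (10), endothelial (1) and liver (1) miRNAs.

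Of 789 miRNAs, 83 passed in limma between SCLC lines and fibroblasts, 29 higher and 54 lower, of which 13 and 52 had at least 1 group mean above background. Adjusted p was 1.18e-05 for miR-9-5p, 0.0381 for miR-375, 0.00859 for miR-95, 8.51e-06 for both miR-183-5p and miR-96-5p, 4.91e-05 for miR-182-5p and 1.82e-08 for miR-145-5p. It was 6.31e-05 for the shared miR-199 probe, 9.36e-07 for miR-143-3p, 3.19e-05 for miR-100-5p, 0.00429 for miR-221-3p, 0.000108 for miR-29a-3p, 0.000147 for miR-29b-3p, 1.15e-07 for miR-155-5p and 0.00174 for miR-337-5p. Without MRC-9 the count was 39 and without WI-38 it was 25. Either omission ended the calls of miR-375 (5.80 and 5.96, adjusted p = 0.283 and 0.318), miR-95 (5.43 and 5.25, adjusted p = 0.134 and 0.196), miR-221-3p (-6.78 and -7.11, adjusted p = 0.125 and 0.130) and miR-337-5p (-5.66 and -5.46, adjusted p = 0.0609 and 0.108). With only the 17 SCLC lines of run 1 the count was 48 and miR-375, miR-95 and miR-221-3p were not called (adjusted p = 0.177, 0.0712 and 0.0513). With centring and the block miR-375 was not called (adjusted p = 0.0527), and with the run as a block 62 were higher and 70 lower (16.7% of the miRNAs tested, against 10.5%). The split was 54 higher and 27 lower with voom and 15 and 68 after centring on the 100 most abundant miRNAs, which moved the median difference from 0.03 to 0.59 and -0.49, and centring on the miRNAs above the floor in every sample moved it to 0.24.

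The labels name NSCLC lines as comparators for the SCLC lines. Here the oncogenic miR-17-92 cluster and its paralogs, which are induced by MYC and promote cell cycle entry, were higher in SCLC lines in 7 of 11 probes, with 9 passing when adjusted over the list alone. The level of miR-19a-3p was 10.23 ± 1.37 (n = 64) against 5.56 ± 1.84 (n = 2), a difference of 4.67 (63 of 64 lines). The NSCLC mean lies below background but its spread crosses that level, so no bound on the fold is given. In the same list miR-18a-5p was higher by at least 3.47 log2 units (64 lines), miR-19b-3p by 14.5-fold (62 lines), the probe shared by miR-106a-5p and miR-17-5p by 8.45-fold (63 lines) and miR-93-5p by 7.41-fold (64 lines). Outside the list miR-301a-3p was 7.98-fold higher (64 lines). The neuroendocrine miR-375 was 9.92 in SCLC lines and 4.88, below background, in NSCLC lines, at least 4.16 log2 units apart, without passing the test (adjusted p = 0.274), and 56 lines lay above both NSCLC lines.

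The miR-17-92 list passed camera, also with the listing run as a block, and with an estimated correlation (adjusted p = 0.00447, but 0.153 without NCI-H1650 and 0.000267 without NCI-H2066). Its median difference was 2.89, and 1.89 after centring, 1.84 after quantile normalization and 1.86 with the block. Camera also called the miR-183 cluster, the miR-200 family, the neuronal and neuroendocrine list and the miR-15/16 family higher in SCLC lines, although 0 of their 26 members passed alone in limma. Adjusted over the list alone, 3 of 3, 3 of 5, 4 of 13 and 0 of 5 passed. With an estimated correlation none of these 4 lists did (adjusted p = 0.162, 0.361, 0.131 and 0.298 with an estimated correlation). The median difference of the neuronal list, 0.72, turned to -0.29 through the shift of all miRNAs by centring but stayed 0.87 above that of all miRNAs, where camera called it again (adjusted p = 0.000225, and 0.0586 with an estimated correlation). With the run as a block the neuronal and miR-15/16 lists did not pass (adjusted p = 0.0623 and 0.0524). The miR-29 and miR-30 lists then passed as lower in SCLC lines (adjusted p = 8.14e-05 for each, and adjusted p = 0.0204 and 0.0995 with an estimated correlation). Their median differences were -3.36 and -1.47 with the block, and -2.18 and -0.43 without it, where adjusted p = 0.759 for each with an estimated correlation. Without NCI-H2066 the miR-200 family did not pass (adjusted p = 0.0550), and its member miR-200c-3p went from 2.87 to -1.09, neither called. In the blood and immune list 1 of 11 fell (miR-146a-5p), a call that rested on 1 of the NSCLC lines, since the difference of -2.14 was 0.12 without NCI-H2066 and -4.40 without NCI-H1650. No member passed in limma among miR-29 (3, with 1 lower when adjusted over the list alone), miR-30 (5, with 1 lower likewise), fibroblast (13), other epithelial (6), let-7 (9), miR-34 and miR-449 (7), HOX (6), pluripotency (10), muscle (7), DLK1-DIO3 (56), C19MC (43), miR-506 to miR-514 (21), endothelial (1) and liver (1) miRNAs. Of these, miR-29b-3p (-3.31, adjusted p = 0.104) and miR-30a-5p (-3.43, adjusted p = 0.119) were called lower after centring (-4.32 and -4.43, adjusted p = 0.00903 for each) and after quantile normalization (-3.64 and -4.67, adjusted p = 0.0301 and 0.00924). Without NCI-H1650 (-4.57 and -5.15) or NCI-H2066 (-2.05 and -1.70) neither was called.

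In limma 12 of 789 miRNAs passed between SCLC and NSCLC lines, 11 higher and 1 lower, and 90 had an unadjusted p under 0.05. Adjusted p was 0.00362 for miR-19a-3p, 0.0111 for miR-18a-5p, miR-19b-3p and miR-93-5p, 0.0191 for the shared miR-106a-5p and miR-17-5p probe and for miR-146a-5p, and 0.0189 for miR-301a-3p. With the listing run as a block limma called 0 miRNAs, while voom without the block called 14. In the blocked fit 35 had an unadjusted p under 0.05, no more than 789 unchanged miRNAs would give on average. There the fitted differences of miR-19a-3p and miR-18a-5p, 4.67 and 4.25 before, became 3.22 (adjusted p = 0.0586) and 3.28 (adjusted p = 0.0683). Against only the 8 SCLC lines of run 5 the count was 1, a miRNA lower in SCLC lines, and 0 of the 12 calls were kept. Without NCI-H1650 the count was also 1, and without NCI-H2066 it was 3, namely miR-19a-3p, miR-19b-3p and the probe shared by miR-20a-5p and miR-20b-5p. Without NCI-H1650 the difference of miR-19a-3p was 3.37 (adjusted p = 0.517), that of miR-19b-3p 2.40 (adjusted p = 0.929), that of miR-18a-5p 3.63 (adjusted p = 0.457), that of miR-93-5p 3.05 (adjusted p = 0.282), that of miR-301a-3p 3.39 (adjusted p = 0.282) and that of the shared miR-106a-5p and miR-17-5p probe 2.27 (adjusted p = 0.929). Without NCI-H2066 the calls of miR-18a-5p (4.87, adjusted p = 0.109), miR-93-5p (2.73, adjusted p = 0.503), miR-301a-3p (2.60, adjusted p = 0.955) and the shared miR-106a-5p and miR-17-5p probe (3.89, adjusted p = 0.112) ended. Centring moved the median difference of all miRNAs from -0.16 to -1.16 and the split to 6 higher and 6 lower. The split was 5 and 17 after quantile normalization, 2 and 8 after centring on the 100 most abundant miRNAs, 8 and 6 with voom, and 1 and 2 with centring and the block. Of the 12 calls, 7 were kept after centring, 5 after quantile normalization and 3 on the 100 most abundant miRNAs. Among those with an adjusted p given above, the shared miR-106a-5p and miR-17-5p probe was not called after centring (2.08, adjusted p = 0.186). After quantile normalization neither this probe nor miR-301a-3p was called (1.75 and 1.51, adjusted p = 0.177 and 0.0585). On the 100 most abundant miRNAs miR-18a-5p, miR-19b-3p and miR-301a-3p (adjusted p = 0.0760 for each) and that probe (0.0988) were not called.

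**Figure D3:**
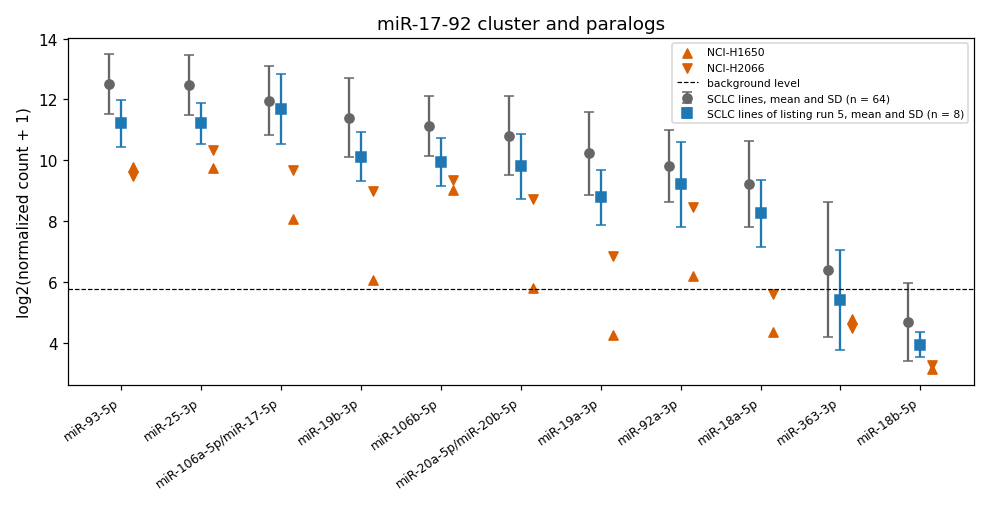
Level (log2 normalized count) of the 11 probes of the miR-17-92 cluster and its paralogs in SCLC lines (mean ± SD, n = 64), in the 8 SCLC lines of run 5 and in the 2 NSCLC lines. The list mean is 10.06 in all SCLC lines, 9.05 in those of run 5, 6.48 in NCI-H1650 and 7.76 in NCI-H2066.

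Among the miRNAs called in both the lung and the fibroblast comparison, 6 were higher in SCLC lines in each (miR-9-5p, miR-182-5p, miR-96-5p, miR-301a-3p, miR-196b-5p and miR-1908) and 19 were lower in each, including miR-143-3p, miR-145-5p, miR-29a-3p, miR-155-5p and miR-34a-5p. Both means of miR-1908 lay below background in each comparison. Against normal lung the call of miR-155-5p ended after quantile normalization, with voom, and with centring and the run as a block. Independent lists of the same lengths would share 1.18 and 6.23 miRNAs. In 20 simulations of unchanged groups against the same SCLC lines at most 0 were shared. Unchanged groups give few calls after adjustment, so these simulations set no chance level for groups that differ. With the SCLC lines divided so that each comparison used 32 of its own, 3 higher and 20 lower miRNAs were shared. The lung and NSCLC comparisons shared miR-301a-3p among higher and miR-146a-5p among lower calls (0.446 and 0.115 by independent lists, 1 and 2 with divided lines), and the fibroblast and NSCLC comparisons shared miR-25-3p and miR-301a-3p among higher calls (0.404 by independent lists, 4 with divided lines). Against NSCLC these 2 calls were kept in 6 and 12 of 16 settings that left no comparator out. The call of miR-25-3p against fibroblasts ended when either fibroblast line was left out.

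The 3 made-resistant lines were set beside their parent NCI-H69. All 3 had lower levels of the DLK1-DIO3 cluster, a maternally expressed imprinted miRNA cluster, in which 31 of the 34 members detected in NCI-H69 were at least 1 log2 unit lower in every derivative. The median change of these 34 members was -4.22 in NCI-H69/CPR, -2.24 in NCI-H69/LX10 and -4.05 in NCI-H69VCR/R, against -0.84, -1.16 and -1.11 for the other detected miRNAs. Of these members 32, 17 and 30 lay below background in the derivatives in that order, and with such values set to the background level the medians were -2.64, -1.93 and -2.64 and 24 members met the limit. In the 10 miRNAs with the largest mean differences the derivatives' mean lay below background, so their order has no meaning. The cluster members miR-485-3p and miR-543 had levels of 9.65 and 9.96 in NCI-H69. They lay below background in NCI-H69/CPR and NCI-H69VCR/R, at least 14.8-fold and 18.3-fold lower. In NCI-H69/LX10 they stayed above background, with changes of -3.15 and -2.51. Outside the cluster miR-660-5p (8.61) and miR-148a-3p (8.25) lay below background in all 3 derivatives, the former lower by at least 7.21-fold. By list, with members counted if above background in the parent or a derivative, 6 of 9 miR-17-92 miRNAs were lower by the same limit, but the median change of the list, -1.37, turned to 1.06 once the difference between listing runs was taken off. Under that setting 0 of 9 were lower and 2 higher, and 0 of 9 were lower or higher after centring or quantile normalization. The let-7 family had 3 of 9 lower, including let-7b-5p (-2.89 ± 0.05) and let-7a-5p (-1.96), and 2 of 9 under each other scaling. Its median of -1.03 turned to 0.42 after quantile normalization. Of 3 HOX cluster miRNAs 2 were lower, and 1 under each other scaling. In the miR-200 (5), miR-30 (3) and blood (3) lists 1 member each was lower, and the medians of -0.89, -1.03 and -1.18 turned to 0.54, 0.24 and 0.71 with the run difference taken off (the former pair also to 0.30 and 0.28 after quantile normalization). Under each other scaling 0 members of these 3 lists were lower. In the miR-200 list 1 was higher after centring, and 2 after quantile normalization and with the run difference taken off. Of miR-30 miRNAs 1 was higher after centring, and of blood miRNAs 1 with the run difference taken off. Of 8 neuronal and neuroendocrine miRNAs 1 was higher, miR-7-5p (1.54 ± 0.05), and 2 were lower, with a median of -0.23 that turned to 0.52 after quantile normalization and above 0 under each other scaling. None of the 8 was lower under the other scalings, where 3 were higher after centring, 2 after quantile normalization and 2 with the run difference taken off. In the miR-29 list 1 of 3 was higher while the median of -0.20 turned to 0.71 after quantile normalization and likewise above 0 under the others. No member met the limit in the miR-183 (3), miR-15/16 (3), fibroblast (8), other epithelial (1), miR-34 and miR-449 (1), pluripotency (1) and C19MC (1) lists, and the endothelial, muscle, liver and miR-506 to miR-514 lists had 0 members above background. After quantile normalization 2 of 3 miR-183 and 2 of 3 miR-15/16 miRNAs and the pluripotency miRNA were higher (medians 2.02, 1.23 and 1.83). With the run difference taken off 1 of 3 miR-183 and 1 of 3 miR-15/16 miRNAs were, and after centring 1 of 3 miR-183 miRNAs and the pluripotency miRNA.

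Of the 800 miRNAs, 92 were higher and 100 lower than in NCI-H69 by at least 1 log2 unit in all 3 derivatives, of which 8 and 76 lay above background in the parent or a derivative. With the difference between the SCLC lines of the runs taken off the counts were 73 and 70, of which 69 were among these calls, and after quantile normalization 73 and 63, of which 95 were. The parent was 1 sample, so no test was made and the differences have no replicate check on the parent's side. None of 10000 random lists of 34 miRNAs matched on level had a median as low in any derivative (lowest -1.47, -1.83 and -1.63). NCI-H69 and its derivatives lie in different listing runs, and a run effect on the cluster could not be tested, since the cluster mean lay below background in 13 of the 17 SCLC lines of run 1 and 7 of the 8 of run 5. With the difference between these lines taken off, 30 of the 34 members were lower, with a median of -2.97, a value that for the same reason does not test a run effect. Centring moved the median change of all miRNAs from 0.14 to 0.99 and the split to 288 higher and 35 lower, with 21 cluster members lower and a median of -2.61. After quantile normalization 19 cluster members were lower, with a median of -2.56.

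**Figure D4:**
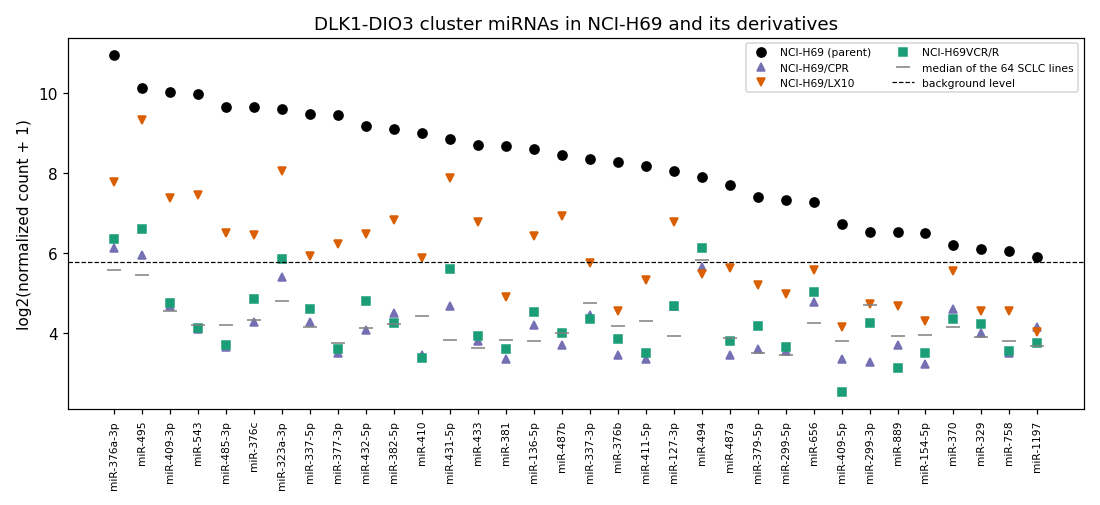
Level (log2 normalized count) of the 34 DLK1-DIO3 cluster miRNAs detected in NCI-H69, in NCI-H69, its 3 made-resistant derivatives and as the median of the 64 SCLC lines. The cluster mean is 8.25 in NCI-H69 and changes by -3.44 on average in the derivatives.

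Normal adrenal RNA lay at least 1 log2 unit outside the range of the 64 SCLC lines for 25 miRNAs, 11 above and 14 below. Blood and vessel miRNAs were among those above, with miR-451a at 14.31 (highest SCLC line 4.17), miR-223-3p at 11.57 and miR-126-3p at 12.42. Below the range were miR-182-5p (2.21), miR-301a-3p (3.33) and miR-92a-3p (4.39). The mesothelioma line NCI-H28 exceeded the range for 4 miRNAs, including miR-30a-5p (12.98), miR-29b-3p (14.64) and the inflammatory regulator miR-146a-5p (7.95), and lay below it for 62, including miR-9-5p (3.57) and miR-196b-5p (0). Of these 62, only 3 were miRNAs detected on either side, and after quantile normalization the total was 7, not 66. Each of these was 1 sample and was not tested. Each SCLC line set against the other 63 in the same way gave a median of 1 miRNA and at most 31, and 1 line gave as many as normal adrenal.

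Among the 64 SCLC lines 4 of the 5 epithelial miR-200 family miRNAs had the largest SDs. The SD was 3.74 for miR-200c-3p (range 3.41 to 15.49), 3.59 for miR-200b-3p, 3.25 for miR-200a-3p, 3.19 for miR-141-3p and 2.81 for miR-429, against a median SD of 1.05 over 355 miRNAs with a median above the floor. Other variable miRNAs were miR-216b (2.98), miR-135a-5p (2.95), miR-375 (2.92, range 2.83 to 14.71), miR-217 (2.64) and miR-221-3p (2.61). Of the 800 miRNAs, 37 lay above background in all 64 lines, 465 in none and 298 in some. The leading principal component held 22.6% of the variance, with the miR-200 family and miR-375 at 1 end, and correlated with the summed normalized count of the lines (r = 0.852), with 29.5% of it lying between listing runs. The third component had DLK1-DIO3 miRNAs at 1 end.

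Levels of miR-375 fell into separate clusters, a low one of 14 lines (mean 5.04) and a high one of 50 lines (mean 11.28), and the mean of the miR-200 family likewise into 14 low and 50 high lines (means 3.94 and 10.94). In 45 lines both were high, in 9 both were low and in 10 only 1 was high. Relations were therefore given within clusters. In the 45 lines high in both, miR-375 rose with the miR-200 family mean (Pearson r = 0.498, permutation adjusted p = 0.0102, Spearman rho = 0.467, adjusted p = 0.0212). Without the 2 farthest lines r was 0.438, and within the 5 listing runs with at least 6 such lines r ranged from 0.347 to 0.912. In the 50 lines high in miR-375, it rose with miR-21-5p (r = 0.565, permutation adjusted p = 0.00148, rho = 0.592, adjusted p = 0.000370), with r of 0.544 without the 2 farthest lines and 0.367 to 0.818 within runs. It also rose with the let-7 family mean (r = 0.435, permutation adjusted p = 0.0207, rho = 0.436, adjusted p = 0.0212), with 0.378 without the 2 farthest lines and -0.132 to 0.908 within runs, 4 of 5 being above 0. With miR-22-3p it rose as well (r = 0.410, permutation adjusted p = 0.0289, rho = 0.401, adjusted p = 0.0385), with 0.386 without the 2 farthest lines and 0.127 to 0.797 within runs. In the 14 lines low in miR-375 the values were below 0 without passing, for miR-21-5p r = -0.475 (permutation adjusted p = 0.263, rho = -0.415, adjusted p = 0.432), for let-7 r = -0.429 (adjusted p = 0.334, rho = -0.345, adjusted p = 0.556) and for miR-22-3p r = -0.528 (adjusted p = 0.263, rho = -0.459, adjusted p = 0.368). In the 9 lines low in both miR-375 and the miR-200 mean r was 0.201 (exact permutation adjusted p = 0.795, rho = 0.217, adjusted p = 0.716). Differences between the clusters were not tested.

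These 4 of 37 tests over 16 relations passed after adjustment in both measures, and 6 had an unadjusted permutation p under 0.05 for r. The relation with the miR-183 cluster mean missed it (r = 0.374, permutation adjusted p = 0.0524), and no test passed for the means of the miR-17-92, miR-221 with miR-222 and DLK1-DIO3 lists, for the relation of the miR-200 mean with the mean of miR-221 and miR-222, or for miR-7-5p, miR-9-5p, miR-95, miR-124-3p, miR-31-5p, miR-155-5p and miR-34b-3p. After quantile normalization r was 0.324 with the miR-200 mean (adjusted p = 0.220), 0.211 with let-7 (adjusted p = 0.578) and 0.354 with miR-22-3p (adjusted p = 0.134), and 0.443 with miR-21-5p (adjusted p = 0.0405). After adjustment for the summed signal it was 0.499 with the miR-200 mean (adjusted p = 0.0122), 0.406 with miR-21-5p (adjusted p = 0.0475), 0.179 with let-7 (adjusted p = 0.414) and 0.361 with miR-22-3p (adjusted p = 0.0948). Centred within each run it was 0.352 with miR-22-3p (adjusted p = 0.0630). In the 14 low lines, where miR-375 lay mostly below background, miR-375 and the miR-183 cluster mean (r = 0.676, permutation adjusted p = 0.0532) passed after quantile normalization and after adjustment for the summed signal. Centring within runs let miR-155-5p pass in these low lines and miR-95 in the lines high in both.

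**Figure D5:**
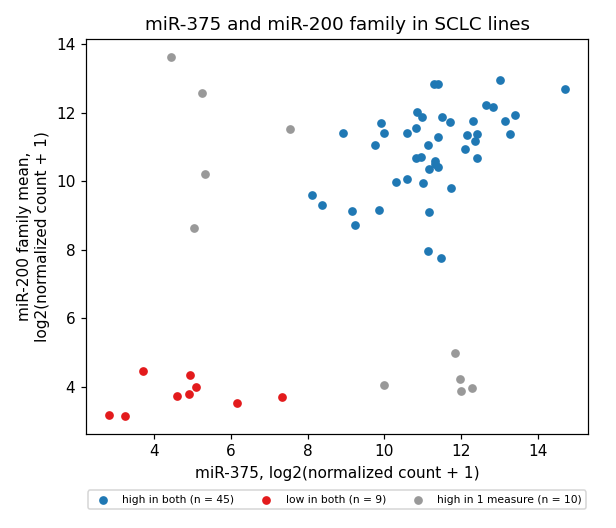
Level of miR-375 (horizontal axis, log2 normalized count) against the mean of the 5 miR-200 family miRNAs (vertical axis, log2 normalized count), 1 point per SCLC line (n = 64). In 45 lines both are high and in 9 both are low, and the correlation within the former is 0.498.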

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

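The tests with values set to the background level, the stricter background filter, the 100 most abundant miRNAs, voom, centring with the block, centring of the lists, of the made-resistant lines, of the single samples and of the SDs, the lists without each comparator, the run difference taken off, and the relations without COR-L47 or adjusted for signal were chosen only after the data were seen. Of the alternative values of main results 55 stayed within their limits and 41 moved, and of the values of named miRNAs and of counts by direction 1523 stayed, 187 lost a call, 63 gained 1, 62 moved and 1 called value changed direction, that of miR-146a-5p against NSCLC (0.12 without NCI-H2066 and -4.40 without NCI-H1650). Values never called also changed sign, 15 over 5 pairs of a miRNA and a comparison, and 29 of relations. Among them against NSCLC were miR-200c-3p, 2.87 to -1.09 without NCI-H2066, and miR-205-5p, -2.70 to 1.61 without NCI-H1650. Of named calls, 18 of 33 against lung, 19 of 25 against fibroblasts and 0 of 12 against NSCLC were kept under every setting that left no comparator out. Calls against normal lung (123, 15.6% of tested miRNAs) were 473 (59.9%) when centred, 273 (34.6%) centred on the 100 most abundant miRNAs, 434 (55.01%) with voom, 276 (34.98%) with centring and the block, and 62 to 85 (7.86% to 10.8%) with a comparator left out. Calls against fibroblasts (83, 10.5%) were 48 (6.08%) with the lines of the same run, 62 higher and 70 lower (16.7%) with the run as a block and 25 to 39 (3.17% to 4.94%) with a comparator left out. Calls against NSCLC (12, 1.52%) were 22 (2.79%) after quantile normalization, 34 (4.31%) with low values set to the floor, 1 (0.127%) with the lines of the same run, 0 with the run as a block in limma (35 at an unadjusted p under 0.05), 3 (0.380%) with centring and the block, 32 (4.06%) with NCI-H28 added and 1 to 3 (0.127% to 0.380%) with a comparator left out. The 1 call against NSCLC with the lines of the same run was lower in SCLC lines and not among the 12. The 35 with the block are no more than 789 unchanged miRNAs would give on average. Setting values to the background level gave 542, 530 and 475 calls (68.7%, 67.2% and 60.2%) in the order lung, fibroblasts and NSCLC, where tied values make variances small by construction, and the background filter gave 52, 47 and 28 of 186 miRNAs (27.96%, 25.3% and 15.1%). Lists called by camera against lung (4) were 2 with an estimated correlation, 10 with fry and 8 with the block, those against fibroblasts (7) were 2 with an estimated correlation, and those against NSCLC (5) were 1 with an estimated correlation and 1 with fry. The 92 higher and 100 lower miRNAs of the made-resistant lines were 49 (6.13%) at 2 log2 units, 99 (12.4%) with low values set to the floor, 67 (8.38%) with low values set to the background level, and 288 higher and 35 lower (40.4%) when centred. The 25 of normal adrenal were 11 at 2 units, and the 66 of NCI-H28 were 15 at 2 units, 7 after quantile normalization and 5 with low values set to the floor. The median SD of 1.05 was 0.98 with low values set to the floor, 0.96 after quantile normalization and 1.10 when centred. Relations passing were 4, and 2 after quantile normalization, of which only that of miR-21-5p was among the 4. Except for tied values, larger size limits and fewer samples, the cause was not tested. Low signal limits the data, since 465 of 800 miRNAs lay below background in all SCLC lines and 38 of the 123 calls against lung had both means below it. The other deposited table was identical and was not run, and a pseudocount of 10 did not apply to values already on the log2 scale. No paired analysis was possible because replicate numbers only name the samples.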

Other observations

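The tests of the summed signal for the miR-17-92 list and of the identity of NCI-H69 were chosen only after the result was seen. Within the SCLC lines NCI-H82 had the lowest let-7 levels for 5 of 9 family members. Its let-7b-5p was 3.50, where the other 63 lines ran from 7.72 to 15.36, its let-7a-5p was 10.29 (others from 11.48), and let-7d-5p, let-7f-5p and miR-98 were 5.00, 6.09 and 4.65. COR-L32 and COR-L47 correlated at r = 0.968 over 201 miRNAs, where the next highest of the 2016 pairs of SCLC lines reached 0.890 and the median pair 0.682. These lines and values were chosen after they were seen.

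Of the C19MC cluster, active in placenta, miR-518b stood out in tissue RNA, at 11.33 in normal lung and 8.41 in normal adrenal against 4.11 in SCLC lines and 4.31 in fibroblasts. The other 42 members had a median of 3.16 in normal lung. Among them miR-1283, at 9.43 there, read from 8.73 to 10.43 over the groups. It had the smallest SD (0.589) of the miRNAs above background in every SCLC line. Whether this even signal reflects expression was not tested. Of the X-linked miR-506 to miR-514 list, miR-514a-3p (8.28) and miR-509-3p (6.55) exceeded all SCLC lines by at least 1 log2 unit in normal adrenal, as miRNAs chosen after their values were seen.

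The higher miR-17-92 list in SCLC than in NSCLC lines, a difference of the list mean of 2.94 (two-sided exact permutation p = 0.000466), was set against technical explanations. The lower summed signal of the NSCLC lines as the whole cause is argued against by the centred difference of 1.94 (exact permutation p = 0.00233 over 2145 splits), although 4 SCLC lines then lay below the higher NSCLC line. A difference between assay runs as the whole cause is argued against by the difference within run 5, 1.93 (exact permutation p = 0.0222 over 45 splits, 8 SCLC and 2 NSCLC lines). This p and the exact permutation p of 0.000466 are the smallest that their numbers of splits allow. All of these p-values come from the samples in which the list was called, so they are no independent evidence for it. The calls of single miRNAs ended, since limma called 0 with the run as a block, where the fitted difference of miR-19a-3p went from 4.67 to 3.22. A tumour type difference may underlie the list, but with 2 NSCLC lines, 1 of them mixed, it stays an untested hypothesis.

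The lower DLK1-DIO3 cluster in all 3 made-resistant lines was weighed in the same way. A shift of all miRNAs is argued against by matched random lists, since the percentile of the cluster median was 0 in each derivative. A run effect on these probes stays open, since the cluster mean of SCLC lines differed by -0.48 (SE 0.53) between runs 5 and 1, but 7 of 8 and 13 of 17 of these lines lay below background, where a loss of signal could not show, so that taking this difference off (30 of 34 members lower, median -2.97) tested no run effect. Another parent line stays open, since NCI-H249 (cluster mean 7.17, against 8.25 in NCI-H69) correlated best with each derivative outside the cluster (r = 0.875, 0.910 and 0.822, in the order CPR, LX10, VCR/R) and NCI-H69 ranked 2 of 64 (0.858, 0.867 and 0.808), while over all 201 miRNAs NCI-H69 ranked 19, 2 and 14. NCI-H69 and NCI-H249 correlated with each other at r = 0.887, against 0.682 for the median pair of SCLC lines, so the margins outside the cluster do not tell them apart. The cluster means of the derivatives, 4.13 in CPR, 5.97 in LX10 and 4.32 in VCR/R, lay below that of NCI-H249 too. The cluster was thus lower beside either line, each of which was 1 sample. Loss of expression of the cluster during selection may explain the pattern, or a parent sample that gained it, as 3 other SCLC lines had a higher mean, and with 1 parent sample neither was tested.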
